A study of Homo sapiens with 6 samples.

How the data were processed

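Total RNA of 6 libraries was sequenced on Illumina libraries, 3 from PC3 and 3 from PC3-DR, per the labels' protocols. PC3-DR was derived by exposing PC3 to docetaxel at 4 and 8 nM for 48 h over 5 cycles, then at 8 and 12 nM for 48 h over 12 cycles, then at 10 nM rising by 5 nM steps to 50 nM, and was kept at 40 nM for 1 month, per the labels' protocols. The submitters' processing notes name bcl2fastq, FastQC, fastp, HISAT2, TopHat2, StringTie, featureCounts, limma and DESeq without versions, order or roles. They name the mouse build mm9, although the labels give a human organism, so no coordinate is printed. The annotation release, strand setting and filters are not given in the sources used here. The authors deposited 2 normalized tables, for mRNA and lncRNA transcripts, and the column names equal the sample titles. 0 columns belonged to no sample.

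The deposited values were taken as FPKM from the values themselves, since no header or label names the unit. For 99.7% of mRNA-table and 99.9% of lncRNA-table transcripts above 0 in at least 3 libraries, a whole-number transcript length existed for which each library's value was a whole number of reads per kilobase of that length and per fixed share of the library total. Lengths between 200 and 60000 nt were sought, and a read number counted as whole within the rounding of the deposited decimals, which was always under 0.08 of a read. The same 6 totals served both tables. The recovered reads made up between 65.3% and 74.8% of these totals. In simulated data of 20000 transcripts the recovery returned the true length in 98.6%, and it returned a length for 0% of values without this structure. The simulated values were made and decoded with the same library totals, so the simulation does not test the totals or their common scale, which was chosen from the values. The totals are inferred, and whether they count reads or fragments is open. Limits on values at 0 cover counting error only. In PC3-DR replicate 1, 91.6% of the recovered read numbers of assembled transcripts were even, against between 52.5% and 55.1% in the other 5 libraries, so its total of 43153000 need not measure depth as the others do.

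Transcripts with at least 1 FPKM in at least 3 of 6 libraries were tested within each table with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity trend, two-sided, group as the sole term, and Benjamini-Hochberg adjustment at 0.05. Fold changes on this scale understate changes of low transcripts. Since the values are FPKM, the main test was not a count model, and recovered reads entered only an added fit with limma's voom. Both tests were tried on simulated negative binomial reads built from the real lengths, means and totals, with 200 changed transcripts in each table. The dispersion was the median of well-covered transcripts, averaged over the groups, and need not hold for poorly covered ones. The mRNA-table test on 24882 transcripts recovered 27.4% of 4-fold and 100% of 16-fold changes. The lncRNA-table test on 297429 transcripts recovered 20% of 4-fold and 97% of 16-fold changes. Changed transcripts were drawn from those above the median of mean reads, and the shares cover those that passed the filter. Unchanged transcripts gave 6 calls in the mRNA table and 8 in the lncRNA table. All simulated transcripts shared 1 dispersion and no library was shifted, so these shares need not hold for the real libraries. Group means of library measures were compared with two-sided exact permutation tests (SciPy 1.17.1), whose smallest p is 0.1. Pairs of libraries were checked for identical values, and at most 0.001% of values above 0 were equal, so all 6 were kept as separate samples.

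Groups, tests, gene lists, the alternative settings and the rule for named transcripts were fixed before the data were examined. In the mRNA table that rule takes transcripts with a gene symbol, adjusted p under 0.05, groups that do not overlap and a mean above the median of tested transcripts, and none carried a symbol. In the lncRNA table it takes, by identifier, those of each direction with the largest difference under the same conditions, 2 that rose and 2 that fell. Alternatives covered the pseudocount, the filter, scaling between libraries, the trend, a fold threshold, a replicate block and leaving out each library. Robust hyperparameters, voom on recovered reads, sums per assembled locus and a fit without assembled transcripts were added after seeing the data. Figures were drawn with matplotlib 3.10.9, and decoding used Python 3.11.15, NumPy 2.4.6 and pandas 2.3.3.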

Results

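RNA from PC3, a human prostate cancer cell line that is sensitive to docetaxel, was compared with RNA from PC3-DR, a line derived from PC3 by repeated docetaxel exposure and labelled as docetaxel resistant. Docetaxel is a taxane that stabilises microtubules and blocks mitosis. Each group held 3 libraries. Both deposited tables list levels per transcript in FPKM, a read count scaled for transcript length and library total. The mRNA table held 102731 transcripts with Ensembl identifiers. The lncRNA table held 381961 transcripts, of which 266388 carried assembler numbers, 114306 carried NONCODE identifiers and 1267 carried Ensembl identifiers. Library totals read off the values, rounded, were 16186000, 14627000 and 14411000 for PC3 replicates 1 to 3 and 43153000, 16030000 and 15612000 for PC3-DR replicates 1 to 3. At these totals, 3 reads on a 1 kb transcript correspond to between 0.07 FPKM in PC3-DR replicate 1 and 0.21 FPKM in PC3 replicate 3. The labels do not say whether the libraries of a group came from separate cultures. P-values therefore rest on the spread between libraries, which could be technical.

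Transcripts of the mRNA table had low levels in both lines. On average 26497 ± 3472 of them reached 1 FPKM in PC3 and 23496 ± 7460 in PC3-DR (SD, n = 3 each). The lower PC3-DR mean came from replicate 1 with 14943, since replicates 2 and 3, with 26885 and 28661, lay above the PC3 mean. Assembled transcripts held most of the summed signal of both tables, with 68.3% ± 2.0 in PC3 and 72.5% ± 10.2 in PC3-DR (SD, n = 3 each). NONCODE transcripts held 19.3% ± 0.5 in PC3 and 15.0% ± 8.0 in PC3-DR (SD, n = 3 each). None of 16 such measures (4 transcript classes by 4 measures) separated the groups after Benjamini-Hochberg adjustment of two-sided exact permutation tests, where the lowest adjusted p was 0.8 and the smallest unadjusted p that 3 against 3 allows is 0.1, so that no measure could pass. The exact permutation p was at this floor for 2 of the 16, the median level of Ensembl transcripts of the lncRNA table, which was 0.36 ± 0.05 FPKM in PC3 and 0.21 ± 0.17 FPKM in PC3-DR, and their share of the summed signal, which was 0.10% ± 0.003 and 0.07% ± 0.04 (SD, n = 3 each). Most of both gaps came from PC3-DR replicate 1. In PC3-DR replicates 1 to 3 the median was 0.017, 0.291 and 0.318 FPKM and the share 0.023%, 0.092% and 0.095%. PC3-DR replicate 1 stood apart from the other libraries. Its assembled transcripts had a median of 4.08 FPKM, with 0.93% listed at 0, whereas the medians of the other 5 libraries lay between 1.75 and 2.17 FPKM. Its NONCODE transcripts had a median of 0.03 FPKM, with 48.0% listed at 0, against medians between 0.81 and 1.09 FPKM in the other 5 libraries.

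**Figure D1:**
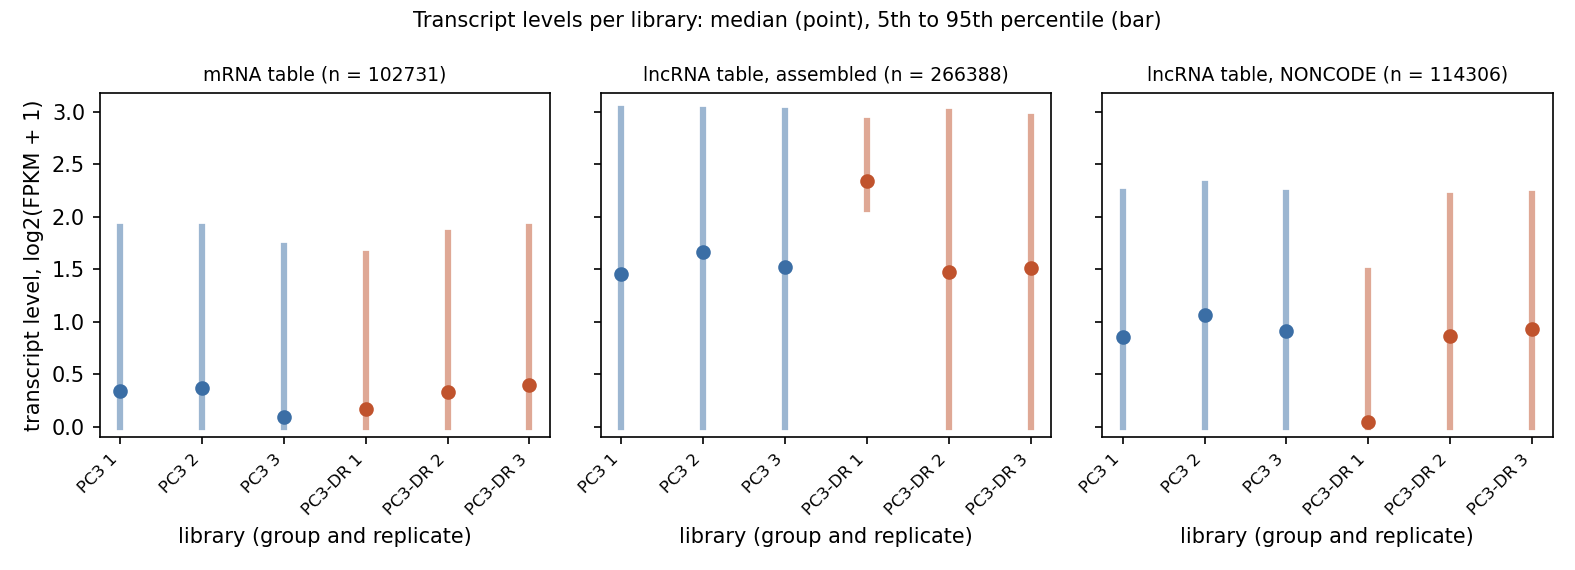
Transcript levels per library on a log2(FPKM + 1) axis, in 3 panels for the mRNA table, the assembled transcripts and the NONCODE transcripts of the lncRNA table. Points are medians and bars span the 5th to the 95th percentile over all transcripts of the panel, with PC3 in blue and PC3-DR in orange; PC3-DR replicate 1 has the highest assembled median (4.08 FPKM) and the lowest NONCODE median (0.03 FPKM).

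Libraries of 1 line resembled each other little more than they resembled the other line. Over 24937 mRNA-table transcripts with at least 1 FPKM in at least 3 libraries, the mean Pearson correlation across transcripts was 0.404 within groups and 0.359 between groups. Single pairs ranged from 0.134 to 0.490. Of the 10 ways to split the 6 libraries into 3 and 3, 3, the real one included, gave a gap at least as large as the real split. Among 241761 assembled transcripts the mean was 0.230 within groups and 0.226 between groups, and among 55397 NONCODE transcripts it was 0.263 and 0.257. Transcripts are not independent replicates, and these values describe the libraries only.

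**Figure D2:**
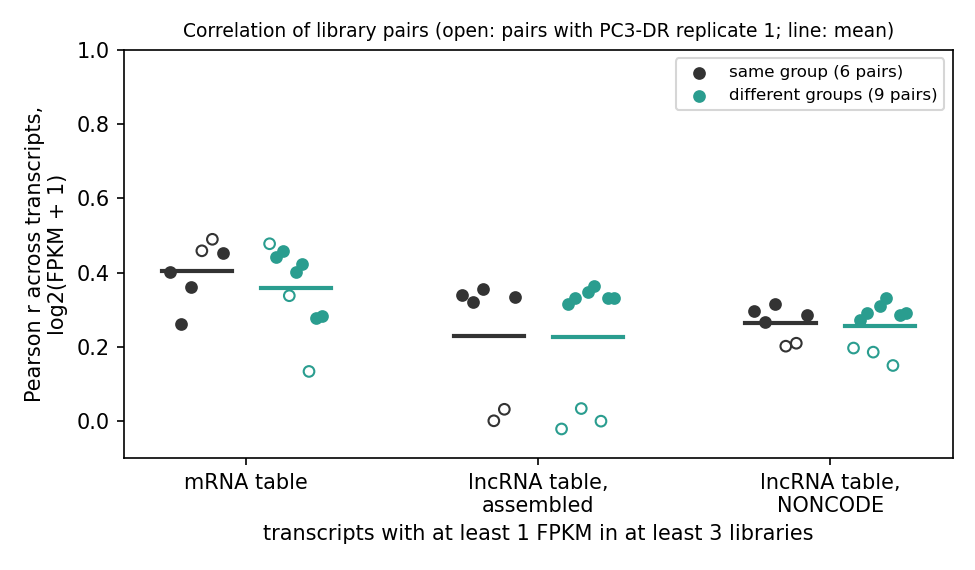
Pearson correlation of log2(FPKM + 1) across transcripts for each of the 15 pairs of libraries, for the mRNA table and the assembled and NONCODE transcripts of the lncRNA table. Dark points are pairs within a group, green points pairs between groups, open points pairs that include PC3-DR replicate 1, and lines the means; within-group means of 0.404, 0.230 and 0.263 lie close to between-group means of 0.359, 0.226 and 0.257.

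The mRNA comparison asked which mRNAs differ between the resistant and the sensitive line. In PC3-DR, 1 of the 24937 tested transcripts rose and 0 fell (limma on log2(FPKM + 1), Benjamini-Hochberg adjusted p under 0.05). This transcript, ENST00000344347, was named after its values were seen, because it was the only one. It was listed at 0 in all 3 PC3 libraries and at 22.6, 12.0 and 9.85 FPKM in PC3-DR replicates 1 to 3. At the inferred totals, these levels correspond to 1104, 218 and 174 reads on a length of 1131 nt. The fitted difference on the log2(FPKM + 1) scale, which depends on the pseudocount because PC3 is at 0, was 3.90 ± 0.39 (SE), with an adjusted p of 0.0342 in limma. At an unadjusted p under 0.05 the limma test gave 1520 transcripts, or 6.1% of those tested. All 3 values of one group lay above all 3 of the other in 11.1% of tested transcripts, where chance gives 10.0%. The call on ENST00000344347 was lost in 14 of 16 alternative settings, including each one that left out a library, where the difference stayed between 3.57 and 4.13. Over all 16 settings its adjusted p in limma lay between 0.0154 and 0.296. The median difference over all tested transcripts was -0.13 on the log2 scale as deposited and 0.00 after rescaling by the median of ratios.

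The lncRNA comparison asked the same of non-coding transcripts. In PC3-DR, 58 of 297498 tested transcripts rose and 101 fell in limma at an adjusted p under 0.05, 159 in all. Directions are those of mean log2(FPKM + 1), and 2 of the 58 had a lower mean FPKM in PC3-DR. Assembled transcripts made up 143 of the calls (47 rose, 96 fell) and NONCODE transcripts 16 (11 rose, 5 fell), while 0 of 340 tested Ensembl transcripts of this table passed. The 159 calls came from 115 loci, counting isoforms of 1 assembled locus together. The groups did not overlap in 79 of the 159 calls. Over all tested transcripts they did not overlap in 9.7%, where chance gives 10.0%. At an unadjusted p under 0.05 the limma test gave 13339 transcripts, or 4.5% of those tested. Other splits of the 6 libraries into 3 and 3 gave between 91 and 143 calls, so most of such a count can arise without a difference between the lines. With the values rescaled by the median of ratios, 24 rose and 74 fell, and the median difference over all tested transcripts moved from 0.10 to -0.01 on the log2 scale. The median difference was 0.21 among assembled and -0.35 among NONCODE transcripts, and it was -0.04 and -0.05 without PC3-DR replicate 1.

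NONHSAT000089.2 was listed at 0 in all 3 PC3 libraries and at 121.0, 258.2 and 14.7 FPKM in PC3-DR replicates 1 to 3. NONHSAT222400.1 stood at 4.19, 1.43 and 5.43 FPKM in PC3 and at 499.9, 6.61 and 2216 FPKM in PC3-DR, so that PC3-DR replicate 2 lay just above the highest PC3 library. MERGE.17971.21 was listed at 90.4, 106.7 and 25.7 FPKM in PC3 and at 0 in all 3 PC3-DR libraries. It is 1 of 21 isoforms that the lncRNA table lists for its assembled locus, whose sum was 549.9 ± 129.6 FPKM in PC3 and 352.3 ± 164.6 FPKM in PC3-DR (SD, n = 3 each, adjusted p = 0.999 in limma on locus sums). MERGE.138.24 was listed at 46.3, 60.4 and 53.9 FPKM in PC3 and at 0 in all 3 PC3-DR libraries. The sum of the 3 isoforms that the lncRNA table lists for its locus was 319.3, 207.0 and 348.8 FPKM in PC3 and 159.2, 0 and 289.3 FPKM in PC3-DR replicates 1 to 3, with a difference of -2.99 on the log2(FPKM + 1) scale (adjusted p = 0.000653 in limma on locus sums). In these locus sums the groups overlapped, and the value of 0 in PC3-DR replicate 2 weighs most in the difference. Locus sums leave out any isoform that is unlisted or carries another kind of identifier. The fitted differences on the log2(FPKM + 1) scale were 6.31 ± 0.40, 5.56 ± 0.41, -6.00 ± 0.41 and -5.76 ± 0.42 (SE) in the order given, each with an adjusted p of 5.39e-38 or less in limma. Leaving out single libraries moved them to between 5.45 (without PC3-DR replicate 2) and 7.48 (without PC3-DR replicate 3) for NONHSAT000089.2, between 3.84 (without PC3-DR replicate 3) and 7.93 (without PC3-DR replicate 2) for NONHSAT222400.1, between -6.63 and -5.63 for MERGE.17971.21 and between -5.86 and -5.67 for MERGE.138.24. These SEs and p-values rest on a spread taken wholly from the trend over all transcripts, since limma estimated an infinite number of prior degrees of freedom. They leave out each transcript's own spread between libraries, also for NONHSAT222400.1, whose PC3-DR values ran from 6.61 to 2216 FPKM. With voom on recovered reads, which was added after the data were seen, the 4 differences were 11.69, 5.90, -11.23 and -11.68 on the scale of log2 counts per library total, all 4 had an adjusted p of 0.131, and 0 transcripts of the table passed, with 20932 at an unadjusted p under 0.05. Without PC3-DR replicate 1, 8 transcripts passed in limma. MERGE.17971.21 (adjusted p = 0.000604) and MERGE.138.24 (adjusted p = 3.6e-05) were among them. NONHSAT000089.2, with a difference of 5.99 (adjusted p = 0.0614), and NONHSAT222400.1, with a difference of 4.91 (adjusted p = 0.980), were not. Without PC3-DR replicate 2, 243 transcripts passed. Over all alternatives the highest adjusted p was 0.131 for NONHSAT000089.2, MERGE.17971.21 and MERGE.138.24 and 0.999 for NONHSAT222400.1.

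**Figure D3:**
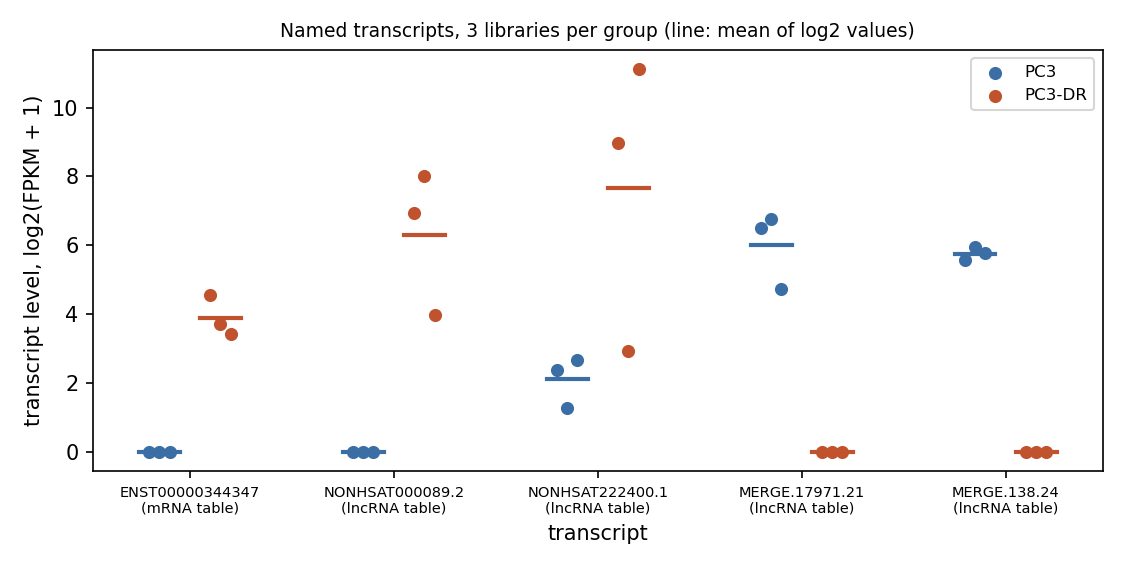
Levels of the named transcripts in each library on a log2(FPKM + 1) axis, with PC3 in blue, PC3-DR in orange and lines at the group means of the log2 values (3 libraries per group). ENST00000344347 and NONHSAT000089.2 are listed at 0 in all 3 PC3 libraries, MERGE.17971.21 and MERGE.138.24 at 0 in all 3 PC3-DR libraries, and for NONHSAT222400.1 the PC3-DR library at 6.61 FPKM lies near the PC3 libraries.

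The series title concerns LINC01963, miR-216b-5p and TrkB, the neurotrophin receptor encoded by NTRK2. The deposited tables give transcript identifiers without gene names, and no table used here pairs these identifiers with names. LINC01963, NTRK2, ABCB1, TUBB3 and the 38 gene lists fixed before the data were examined were therefore not analysed here, and no gene set test was run.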

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

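The fits with robust hyperparameters, voom, locus sums or no assembled transcripts were chosen after seeing the data. In limma 1 mRNA-table transcript passed as planned. 0 passed with a pseudocount of 0.1 or 5, no filter, a filter of 5 FPKM, rescaling by the median of ratios, no trend, or voom on recovered reads, while between 57 and 3008 reached an unadjusted p under 0.05 in these fits. Robust hyperparameters gave 6, quantile normalization 1 and the fold threshold 1. Leaving out single libraries gave between 0 and 1, and the transcript called in the planned fit was in none of those calls. For the lncRNA table the planned 159 became 25 with a pseudocount of 0.1, 9 with no filter, 10 with a filter of 5 FPKM, 98 after rescaling, 43 after quantile normalization, 10 without the trend, 79 with robust hyperparameters, 0 with voom (20932 at an unadjusted p under 0.05), 59 on locus sums and 1 without assembled transcripts. A pseudocount of 5 gave 130 and the fold threshold 159. Leaving out single libraries gave between 8 (PC3-DR replicate 1) and 243 (PC3-DR replicate 2). The differences of the 5 named transcripts kept their direction in every alternative run on them. This was largely fixed beforehand, since the groups do not overlap in these transcripts, and it adds no evidence for them. The cause of the shifts in the counts was not tested.

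Correlations gave no clear sign that replicate numbers pair the libraries, but they cannot exclude it. Deviations of same-numbered libraries correlated at 0.192, -0.004 and 0.093 in the mRNA table and at -0.021, -0.016 and -0.013 in the lncRNA table, and not every library correlated best with its own number. Differently numbered libraries correlated at between -0.182 and 0.113 in the mRNA table. With a replicate block, 0 mRNA-table transcripts passed in limma (1707 at an unadjusted p under 0.05) and 172 lncRNA-table transcripts.

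The DESeq2 alternative was not run because it was set for deposited counts only, and the values used here are FPKM. Sums per gene name, the gene set alternatives and those for LINC01963 and NTRK2 were not run because the tables hold no gene names. Among mRNA-table transcripts with recovered reads, the median was between 6 and 10 reads per library, which limits what single low transcripts can show.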

Other observations

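The tests of even read numbers and of loci with 1 isoform, the random groupings of isoforms, the splits with robust hyperparameters and the counts of transcripts listed at 0 in one line were chosen only after the results were seen.

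Of the 10 splits of the 6 libraries into 3 and 3, 2, the real one included, gave at least as many mRNA-table calls as the real split, which gave 1, and the highest other split gave 2. For the lncRNA table, 1 split of 10, the real one, reached 159, and the highest other split gave 143. 10 splits are too few for a share under 0.05. Every other split of the lncRNA table called at least 91 transcripts. With robust hyperparameters the real split gave 6 mRNA-table calls and the highest other split 2, and for the lncRNA table these counts were 79 and 64. At an unadjusted p under 0.05 the real split gave 13339 lncRNA-table transcripts, with 7 of 10 splits as large and 17814 in the highest, and 1520 mRNA-table transcripts, with 3 of 10 as large and 1771 in the highest.

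PC3-DR replicate 1 stood apart in both tables. Its assembled transcripts had a median log2 ratio of 1.01 to the mean of the other 5 libraries, its NONCODE transcripts one of -2.02 and the tested mRNA-table transcripts one of -1.11, and PC3-DR replicates 2 and 3 had -0.52 and -0.45 in the assembled class, so the shift does not follow the resistant line. A rise in assembled transcripts without a rise in NONCODE transcripts is what a transcript set assembled mainly from this library would give, and the ratios of 1.01 and -2.02 have that form. This source alone need not lower NONCODE transcripts, whose median was 3 recovered reads in PC3-DR replicate 1 and between 12 and 15 in the other 5 libraries. The 5th percentile of PC3-DR replicate 1 among assembled transcripts, 3.21 FPKM, is above the medians of the other 5 libraries. Counting once per mate is a candidate source as well, since 91.6% of its assembled read numbers were even, but that value prompted the idea, and 60.1% of its NONCODE and 48.1% of its mRNA-table read numbers were even, which argues against such counting throughout the library. Whether it holds for assembled transcripts alone cannot be told apart from other sources without the reads, which were not used here.

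The weak correlation between libraries of a group was weighed against 3 sources. Counting noise at low depth is argued against for mRNA-table transcripts that were well covered on average: with a mean of at least 100 reads over the 6 libraries the within-group correlation was 0.571, below the 0.8 set beforehand, and no single pair exceeded 0.685. Single libraries of such a transcript could still hold few reads, which limits this test. Near-uniform background coverage, such as genomic DNA, stays open, because between 59.6% and 62.8% of NONCODE transcripts of at least 5 kb lay within a factor of 2 of the median in the 5 libraries other than PC3-DR replicate 1, between the bounds of 80% and 50% set beforehand. Summing isoforms of 148 assembled loci raised the correlation by 0.301, but random groups of the same sizes raised it by a median of 0.277 and up to 0.321, so this cannot be told apart from the effect of summing. Reads moving between the listed isoforms of an assembled locus cannot act at loci with 1 listed isoform, where the within-group correlation was 0.214 over 240634 transcripts and 0.321 in the pairs without PC3-DR replicate 1. Reads moving to unlisted isoforms or to overlapping transcripts with other identifiers were not tested, so that form of this source stays open.

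Some transcripts were listed at 0 in all libraries of one line and at 1 FPKM or more in all of the other, 113 in the mRNA table (66 at 0 in PC3, 47 at 0 in PC3-DR) and 333 in the lncRNA table (179 and 154). Other splits of the libraries gave between 53 and 138 in the mRNA table and between 309 and 505 in the lncRNA table. Leaving out a library loosens this rule, so the counts could only rise. Leaving out any 1 library gave between 262 and 405 in the mRNA table and between 1075 and 1767 in the lncRNA table. In the lncRNA table those at 0 in PC3 outnumbered those at 0 in PC3-DR without each PC3 library and were outnumbered without each PC3-DR library. This direction followed the line that lost a library, so it says nothing about the lines. Minimum levels of 0.5 and 2 FPKM, which could only raise and only lower the counts, gave 349 and 24 in the mRNA table and 840 and 68 in the lncRNA table. Of the lncRNA-table transcripts, 165 of the 179 at 0 in PC3 were assembled and 137 of the 154 at 0 in PC3-DR were NONCODE transcripts, the classes that were higher and lower in PC3-DR replicate 1. Switching between the listed isoforms of an assembled locus cannot act at loci with 1 listed isoform. From such loci came 174 of the 179 assembled ones (97.2%, against 99.5% of all assembled transcripts). For the 5 others it stays open, since the median absolute log2 difference of 4 locus totals was 0.80, between the bounds of 0.5 and 1 set beforehand. Switching with unlisted isoforms or with overlapping transcripts under other identifiers was not tested. The real split of the libraries did not give the most such transcripts, with 9 of 10 splits as large in the lncRNA table and 3 of 10 in the mRNA table, the real one included.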
